A study of Homo sapiens with 7 samples.

How the data were processed

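Single-cell RNA sequencing of myeloid cells from glioblastoma, a malignant brain tumour, was available for 7 libraries: 3 from the tumour core and 4 from the tumour margin. Per the labels' protocols, tissue was dissociated with papain, red cells were lysed, core and periphery were sorted separately, and 10x Genomics 3' libraries were read as paired ends of 150 bp on a NovaSeq 6000. Per the labels, Cell Ranger 4.0.0 mapped reads to hg38 and made the count matrix, Seurat 4.0.4 was used for analysis, and SingleR 1.0.1 assigned cell types. The deposited table holds raw counts, as UMIs per gene and cell, for 24344 genes and 2990 cells that the authors deposited as myeloid. All values were whole numbers, with 6650 as the highest. How cells were filtered before deposit, and the annotation release, are not given in the sources used here. Raw reads were not used here, and nothing was mapped again. The lowest cell total was 499 UMIs and the highest mitochondrial share was 19.8%.

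Each column of the table was assigned to its library by the start of its name, and all columns were assigned. Titles and the table's first lines pair 3 core libraries with 3 margin libraries: core replicate 1 with margin replicate 2, core replicate 2 with margin replicate 3, and core replicate 3 with margin replicate 4. Margin replicate 1 has no partner in the table. The labels do not say what a pair shares, and the first number in the titles differs within each pair, so a shared patient is an assumption of the paired fit. Deviations from group means in all cells correlated at 0.416, 0.348 and 0.147 within the 3 pairs, but core replicate 3 correlated more with margin replicate 1 (0.372) than with its partner. Sex-linked genes were checked within the 3 pairs and 0 pairs differed. Sex-linked genes and immune receptor segments, 78 genes in all, were kept out of tests, lists and names. Gene positions came from GENCODE release 29 on hg38, which holds 23037 of the symbols and may differ from the release used for counting.

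Cell classes were made in scanpy 1.11.5. Counts were scaled to 10000 per cell and logged, genes seen in at least 10 cells were kept, and the 2000 most variable genes gave 20 principal components and 15 neighbours. Leiden clusters (igraph 0.11.9) at resolution 0.8 were named by the marker list with the highest mean fold, where the list of cycling markers could neither name a cluster nor count as a conflict. A name needed at least 3 markers detected in 10% of cells, and clusters with conflicting markers, low depth, no raised marker list or the highest fold for markers of astrocytes or tumour cells stayed unnamed. Unnamed cells stayed in the comparison of all myeloid cells. Alternatives used resolutions of 0.4 and 1.2, and marker sums per cell. TMEM119-positive cells are those with at least 1 UMI of TMEM119, the marker by which the study picked microglia, per the labels. The study's cell type calls are not in the table and were not used here. Doublets were called with Scrublet in libraries of at least 100 cells, which left out core replicate 2 and margin replicate 2. Calls were uneven: 0.062% and 1.25% of cells in core replicates 1 and 3, and 1.12%, 5.75% and 20.2% in margin replicates 1, 3 and 4.

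Core was compared with margin on counts summed per library, since cells of a library are not independent replicates. Libraries with under 20 cells of a class stayed out. The test was the quasi-likelihood F test of edgeR 4.0.16 with its default low-count filter, TMM factors and a Benjamini-Hochberg threshold of 0.05, with no term for the pairs. The same test with the 3 pairs as a block is called the paired fit, and it leaves out margin replicate 1. DESeq2 1.42.0 and limma 3.58.1 were run beside it, in R 4.3.3. Standard errors are the absolute log2 change divided by the root of F. Shares of cells were compared with exact two-sided permutation tests over the 35 splits of 7 libraries into 3 and 4. The smallest p these can give is 0.0286, and 3 pairs cannot give less than 0.25, so paired shares have no test. Share intervals are exact Clopper-Pearson intervals at 95%. They cover counting error only. A count of 0 was given an upper limit of 3 counts.

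Gene lists were tested on limma voom values with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Of 33 lists, 28 had at least 3 tested genes in all cells. The lists, the cell markers, the tests and the choice of named genes were set before the data were examined. Named genes are the 10 with the largest rise and the 10 with the largest fall among those past the threshold, averaging over 20 CPM (counts scaled to a fixed library total), with no overlap between groups. Where none passed, the 5 with the smallest p in each direction are named. Up to 4 members of each passing list, here 3, and 16 genes on microglia and ATP are named in any case. After the data were seen, the same choice was also applied to the paired fit. Checks on simulated data changed 200 genes, all averaging over 20 CPM, in drawn negative binomial counts. In all cells they recovered 93% of 4-fold and 100% of 16-fold changes without pairs, and 78% and 98% with pairs. Recovery of genes under 20 CPM was not simulated. In that check 19 of 212 unpaired and 16 of 192 paired calls were false. Of 4-fold changes, 83% were recovered without and 72% with pairs in microglia-like cells, and 72% and 36% in TMEM119-positive cells. False calls there numbered 11 of 194 without and 10 of 177 with pairs in microglia-like cells. In TMEM119-positive cells they numbered 7 of 179 without and 19 of 152 with pairs, the last being the largest share of false calls in this check. The simulated counts came from a single draw, held no pair effect and took their spread from a fit without pairs. The paired rates therefore do not show how the paired fit behaves where pairs differ.

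Alternatives were other tools and scalings, other low-count filters, each library left out in turn, means over cells, stricter cell filters, removal of doublets and of cells with markers of other types, and other class definitions. Added after the data were seen were thinning of all sums to the smallest library, the paired fit without each pair, removal of macrophage-like classes, and clusters made without 223 called, hypoxia or glycolysis genes. The planned comparison within monocyte-derived macrophage-like cells, and the test of whether classes differ in their core against margin change, could not be run, since no margin library held 20 such cells. Plots were drawn with matplotlib 3.10.9. Computations in Python 3.11.15 used numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.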

Results

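The table held 1607, 41 and 320 myeloid cells of core replicates 1 to 3, and 536, 64, 313 and 109 cells of margin replicates 1 to 4. Library totals ran from 434374 UMIs in core replicate 2 to 17608088 UMIs in core replicate 1. The other totals were 4598660 UMIs in core replicate 3 and, in margin replicates 1 to 4, 3399712, 818407, 1971247 and 949065 UMIs. Median UMIs per cell were 9907, 7421 and 13156.5 in the core libraries and 4050.5, 13157, 6059 and 8428 in the margin libraries. The series asks how expression differs between tumour core and periphery, and its title concerns ATP released by tumour-associated microglia.

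Microglia-like cells, the resident macrophages of the brain by their markers, made up 34.9% ± 12 (SD, n = 3) of core cells and 53.9% ± 22.9 (SD, n = 4) of margin cells. The margin mean is lowered by margin replicate 1, at 19.8% against 63.3% to 68.8% in the other 3. The share was lower in the core library in 3 of 3 pairs, by 30.4 percentage points on average, which is also the difference of means without margin replicate 1. Cells with TMEM119, a microglia surface marker, made up 32.8% ± 7.83 (SD, n = 3) of core and 46.8% ± 18.1 (SD, n = 4) of margin cells, and were also lower in 3 of 3 pairs, by 22.9 points on average. Margin replicate 1 again stood apart, at 19.96% against 53.2% to 59.4%. Monocyte-derived macrophage-like cells made up 38.6%, 7.32% and 15% of core replicates 1 to 3 and 0.373%, 3.13%, 0.319% and 0.917% of margin replicates 1 to 4. Border-associated macrophage-like cells averaged 14.3% ± 17.3 (SD, n = 3) in core and 7.11% ± 13.2 (SD, n = 4) in margin libraries. Each mean rests on 1 library: core replicate 3 at 34.1% (1.62% and 7.32% in the others) and margin replicate 1 at 26.9% (0% to 0.917%). Without margin replicate 1 the difference was 13.8 points.

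The difference in microglia-like cells, of -19.0 points, had an exact permutation p of 0.229 (adjusted 0.381 over 5 shares). Its size depends on the class definition: -37.7 points at a higher clustering resolution (exact p = 0.0857), -35.7 points by marker sums with no overlap between groups (exact p = 0.0571), -21.0 points at a lower resolution and -15.3 points with called genes left out of the clustering (exact p = 0.286 for both). At the lower resolution the microglia-like share of core replicate 1 was 1.18%, against 27.9%. There 737 cells of core replicate 1 lay in a cluster with its highest fold for microglia markers (0.524), which stayed unnamed for conflicting markers. TMEM119-positive cells differed by -14.0 points, with an exact permutation p of 0.229 (adjusted 0.381). For macrophage-like cells the difference of 19.1 points had an exact permutation p of 0.0286, the smallest the design allows, and 0.143 after adjustment, so it did not pass. The name of that class is weakly supported. It holds a cluster of 456 cells (404 from core replicate 1, 46 from core replicate 3) whose macrophage markers had a mean log2 fold of 0.121, with 0 of them among its top 10 genes, which began with SLC2A1, HILPDA, ADM and HK2, genes induced by low oxygen. It also holds a cluster of 222 cells (217 from core replicate 1) in which cycling markers had a higher mean fold than macrophage markers (1.82 against 0.598). The clusters named microglia-like also had 0 microglia markers among their top 10 genes, at mean log2 folds of 0.484, 0.733, 0.638 and 0.244. The lowest of these folds belongs to 142 cells, 121 of them from core replicate 1, with the heat shock genes HSPA1B and HSPA6 among their top genes. The name of the macrophage-like class was not stable. The difference was 0 at a lower clustering resolution and 11.1 points at a higher resolution (exact p = 0.143). No cluster took this name once called genes were left out of the clustering. The 0 at the lower resolution comes from the naming rule. There a cluster of 830 cells had its highest fold for macrophage markers (0.698) and stayed unnamed for 1 monocyte marker among its top 10 genes. It held 661, 6 and 155 cells of core replicates 1 to 3 and 2 cells of each margin library. Marker sums per cell gave 35.9 points, higher in 3 of 3 pairs with no overlap between groups (exact p = 0.0571), but by that definition 41.1% of margin cells were macrophage-like. Border-like and unnamed cells differed by 7.23 and -7.38 points, with exact permutation p of 0.457 and 0.4 (adjusted 0.457 for both). Cells with markers of other brain or tumour cells are part of all myeloid cells here. In 2 unnamed clusters of 123 and 101 cells, markers of astrocytes or tumour cells had the highest mean log2 fold (1.42 and 2.69), and 89 and 79 of these cells came from margin replicate 1. Cells with at least 2 such markers made up 1.74%, 2.44% and 8.75% of core replicates 1 to 3 and 12.5%, 4.69%, 7.35% and 4.59% of margin replicates 1 to 4.

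Detection of TMEM119 depends on depth, and cells of other classes also had UMIs of it. In core replicate 1, 11.6% of macrophage-like cells (exact interval 9.18% to 14.4%, median 12663 UMIs) had a UMI of TMEM119, against 59.2% of microglia-like cells (54.5% to 63.8%, median 10702 UMIs). Whether those UMIs come from free RNA, misnamed cells or expression was not tested. After thinning each cell to 2000 UMIs the TMEM119-positive share was 11.1% ± 3.82 (SD, n = 3) in core and 22.6% ± 12.3 (SD, n = 4) in margin libraries, and the exact permutation p stayed at 0.229. With at least 2 UMIs required, the difference was -5.29 points and the core library was lower in 2 of 3 pairs.

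**Figure D1:**
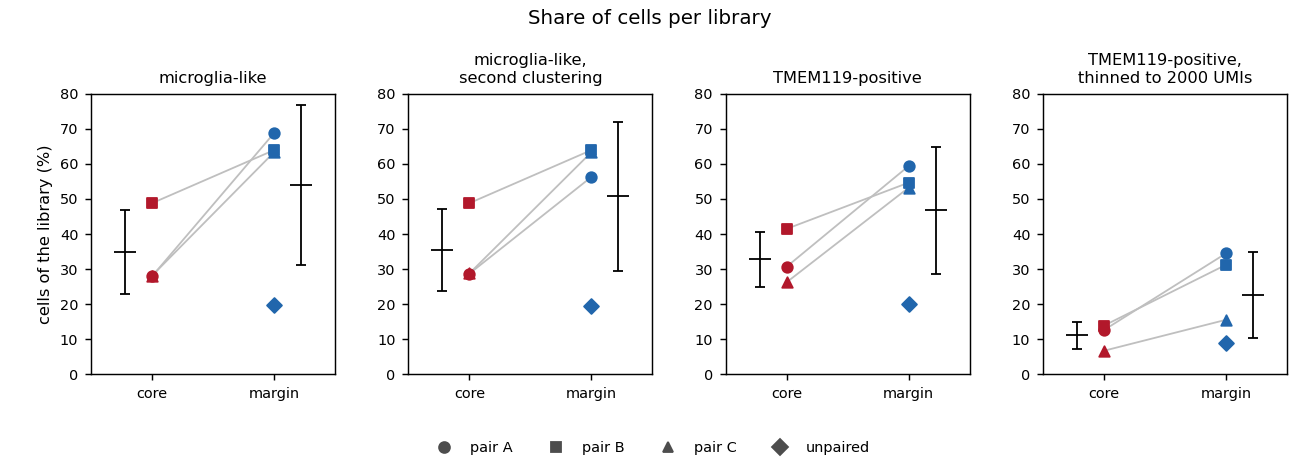
Percent of cells per library that were microglia-like or TMEM119-positive, for core and margin. Microglia-like shares are shown for the main clusters and for the second clustering, made without called genes. TMEM119-positive shares are shown before and after thinning each cell to the same UMI total. Points are libraries, grey lines join libraries of a pair, and black bars are means with standard deviations. The microglia-like and TMEM119-positive shares lie lower in the core library of 3 of 3 pairs.

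Across all myeloid cells, MXI1, a MYC antagonist induced by low oxygen, rose in the core: 74.0 ± 33.8 CPM (SD, n = 3) against 10.3 ± 2.25 CPM (SD, n = 4), a log2 change of 2.86 ± 0.34 (SE) with an edgeR adjusted p of 0.0282. Among genes averaging above 20 CPM alone, a filter fixed beforehand, its change of 2.87 did not pass (edgeR adjusted p = 0.0600) and 0 genes were called. SLAMF9, a leukocyte receptor of the SLAM family, had 604 UMIs in core and 3 in margin libraries, a ratio of 60.7 (95% counting interval 20.7 to 295; edgeR adjusted p = 0.0140). COL27A1, a fibrillar collagen chain, had 334 and 1 UMIs, a ratio of 101 (counting interval 17.9 to 3987; edgeR adjusted p = 0.0282). SLAMF9 and COL27A1 averaged under 20 CPM and fall outside the choice of named genes; they are given because only 3 genes passed. On hg38, MXI1 lies on chromosome 10 from 110207605 to 110287365, SLAMF9 on chromosome 1 from 159951492 to 159954254, and COL27A1 on chromosome 9 from 114155560 to 114312511.

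Of 9981 genes tested without pairs, 3 rose and 0 fell at an edgeR adjusted p under 0.05, and 753 had an unadjusted p under 0.05. DESeq2 called 100 genes, 74 higher and 26 lower in core. These calls rest on few libraries: without core replicate 3 or without margin replicate 4, edgeR called 0 genes (570 and 600 at an unadjusted p under 0.05), without margin replicate 3 it called 1, without margin replicate 1 it called 2, without core replicate 2 it called 9, and without margin replicate 2 it called 21. MXI1 kept a log2 change of 2.39 to 3.04 in these runs, with adjusted p of 0.0644, 0.0594, 0.119 and 0.151 where core replicate 3 and margin replicates 1, 3 and 4 were left out. In 413 genes every core library lay above every margin library and in 341 every core library lay below, 7.55% of the genes against 5.71% by chance.

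With the pairs as a block, edgeR called 191 of 9112 genes, 116 higher and 75 lower in core, including MXI1, SLAMF9 and COL27A1. Genes that rose included FN1, the matrix protein fibronectin, with 209 ± 287 CPM (SD, n = 3) in core and 6.57 ± 11.8 (SD, n = 4) in margin libraries and a paired log2 change of 4.66 ± 0.43 (SE). S100A10, a partner of annexin A2, rose by a paired log2 change of 4.03 ± 0.37 (SE; 1037 ± 426 against 85.2 ± 57.3 CPM). Also higher were the oxygen sensor EGLN3 (4.61 ± 0.54), the lipase inhibitor ANGPTL4 (4.31 ± 0.53), CD109 (4.06 ± 0.53), the mitophagy receptor BNIP3 (3.11 ± 0.57), the stress protein NUPR1 (2.95 ± 0.49), vimentin (VIM, 2.92 ± 0.48), CD52 (2.84 ± 0.37) and the matrix protein TGFBI (2.78 ± 0.25). The adjusted p of these genes ran from 0.00214 to 0.0264 (edgeR). Each was higher in 3 of 3 pairs, which the choice of genes without overlap between groups fixes in advance. Without pairs, their adjusted p ran from 0.0701 for S100A10 to 0.517 for VIM.

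Genes that fell in the paired fit included P2RY12, the ADP receptor of microglia, at 29.2 ± 6.59 CPM (SD, n = 3) in core and 101 ± 18.6 CPM (SD, n = 4) in margin libraries, a log2 change of -1.98 ± 0.26 (SE; edgeR adjusted p = 0.00773). DHRS9, a retinol dehydrogenase, had a log2 change of -3.58 ± 0.37, and CACNA1A, a calcium channel subunit, one of -2.77 ± 0.30. Also lower were LINC01141 (-2.59 ± 0.30), the microglial transcription factor SALL1 (-2.45 ± 0.36), NAV3 (-2.30 ± 0.26), RASGEF1C (-2.07 ± 0.32), the mitochondrial kinase PDK4 (-1.87 ± 0.32), ACSM5 (-1.68 ± 0.35) and KLF2 (-1.63 ± 0.35). CX3CR1, the microglial fractalkine receptor, and the chemokine CCL2 also fell, by paired log2 changes of -2.02 ± 0.29 and -1.96 ± 0.28, although their core and margin ranges overlapped. Without pairs the adjusted p of these genes ran from 0.0574 for P2RY12 to 0.916 for CCL2. Of the 157 paired calls that averaged over 20 CPM, 84 showed no overlap between groups, 61 of them higher in core. Leaving out a pair gave 429, 112 or 60 calls.

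**Figure D2:**
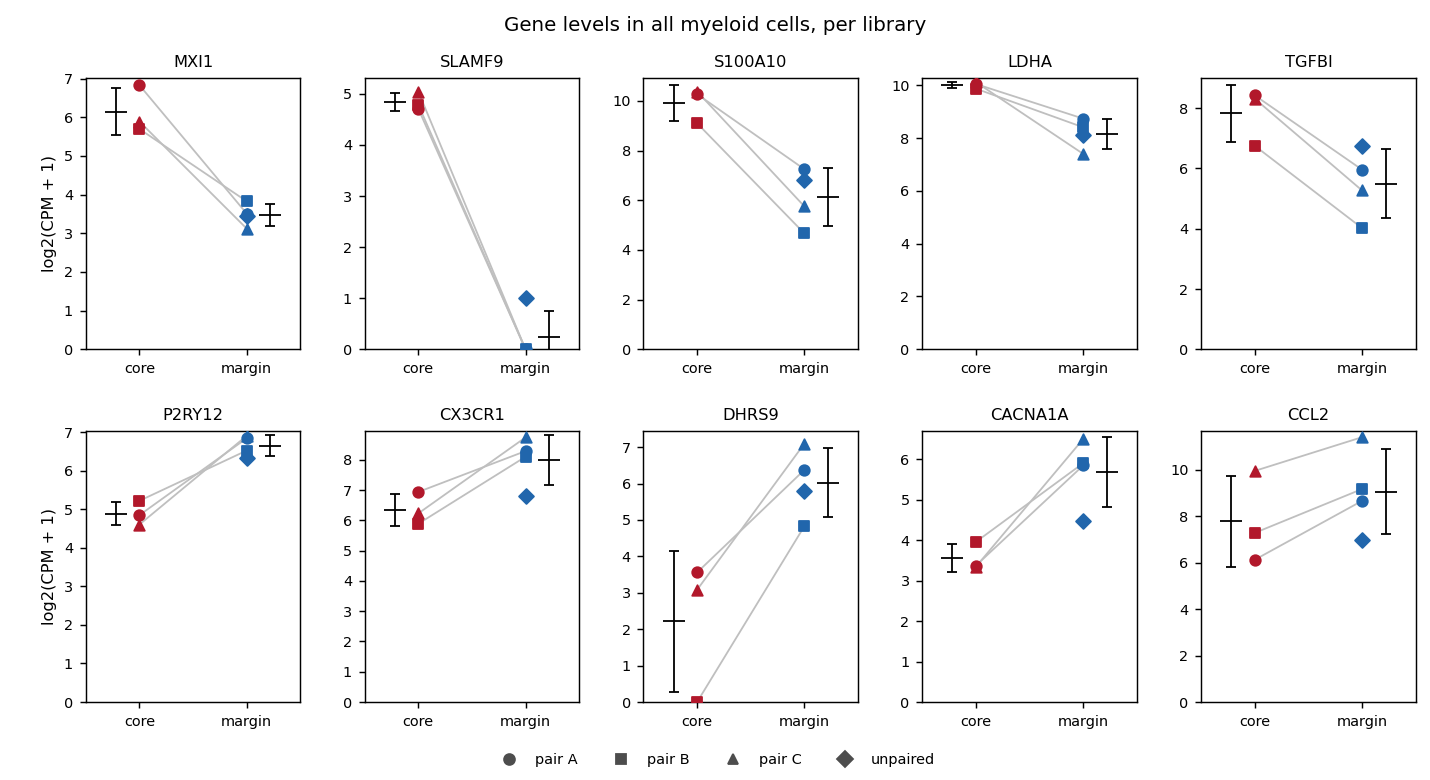
Log2 of CPM plus 1 in all myeloid cells per library for 10 genes; points are libraries, grey lines join pairs, and black bars are means with standard deviations. MXI1 lies at 50.9 CPM or more in the 3 core libraries and at 13.2 CPM or less in the 4 margin libraries.

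Among the gene lists in all cells, the hypoxia response was higher in the core. Of its 22 tested genes 21 were higher, 1 (MXI1) rose over all genes and 15 rose when adjusted over the list alone, with a median log2 change of 1.74. Camera gave an adjusted p of 4.80e-16, with an adjusted p = 0.108 with an estimated correlation. HILPDA, a lipid droplet protein, had a log2 change of 3.92 ± 0.74 (SE) and ANGPTL4 one of 5.16 ± 0.88. The ranges of HILPDA overlapped, as core replicate 2 was at 2.42 CPM and the margin libraries at 2.31 to 5.97 CPM. In the paired fit 8 of 19 members rose over all genes, with a median of 1.03. Glycolysis genes were higher in 17 of 18 cases with a median of 1.16, and 0 passed over all genes and 11 when adjusted over the list alone. Camera gave an adjusted p of 1.04e-14, with an adjusted p = 0.116 with an estimated correlation. LDHA, which makes lactate, reached 1031 ± 89.1 CPM (SD, n = 3) in core and 302 ± 108 CPM (SD, n = 4) in margin libraries, and rose in the paired fit by 1.82 ± 0.31 (SE), as did GPI (1.32 ± 0.24) and PKM (1.23 ± 0.23) among 6 paired calls. Without margin replicate 1 the hypoxia median was 1.15.

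Cell cycle genes were higher in 21 of 21 tested cases, with a median log2 change of 1.10, 0 passing over all genes and 11 when adjusted over the list alone. Camera gave an adjusted p of 2.84e-14, with an adjusted p = 0.108 with an estimated correlation. CDK1, the kinase that drives mitosis, reached 34.9 ± 9.17 CPM (SD, n = 3) in core and 8.29 ± 3.58 CPM (SD, n = 4) in margin libraries and rose in the paired fit by 2.30 ± 0.33 (SE), while RRM2 and AURKB had unpaired changes of 2.28 ± 0.55 and 2.78 ± 0.68. Markers of monocyte-derived macrophages were higher in 12 of 13 cases (median 0.96, camera adjusted p = 0.000106, adjusted p = 0.246 with an estimated correlation). Of them 0 passed over all genes, 1 when adjusted over the list alone and 5 in the paired fit, among them TGFBI and S100A9 (1.90 ± 0.35). Without margin replicate 3 that median was 0.59. This list moved with the share of macrophage-like cells given above.

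Lipid handling and phagocytosis genes were higher in 17 of 24 cases (median 0.37, camera adjusted p = 0.00608, adjusted p = 0.455 with an estimated correlation), with 0 passing over all genes, 1 when adjusted over the list alone and 6 in the paired fit. PLIN2, a lipid droplet coat protein, and the protease CTSL rose in the paired fit by 2.43 ± 0.37 and 1.66 ± 0.32 (SE), while AXL had an unpaired change of -0.67 ± 0.27. Iron and haem genes were higher in 8 of 12 cases (median 0.67, camera adjusted p = 0.0113, adjusted p = 0.246 with an estimated correlation). Of these 0 passed, also when adjusted over the list alone, and 3 rose in the paired fit, among them HAMP, the iron hormone hepcidin (1.57 ± 0.31). Matrix remodelling and angiogenesis genes were higher in 13 of 18 cases (median 0.51, camera adjusted p = 0.0060, adjusted p = 0.246 with an estimated correlation). When adjusted over the list alone, 3 rose (FN1, TIMP1 and TGFBI) and 1 fell. The call was lost without core replicate 3 for lipid handling (0.27), iron (0.53) and matrix genes (median 0.04), and without margin replicate 4 for lipid handling (0.22) and iron (0.54). The matrix median also moved to 0.90 without core replicate 1, 0.15 without margin replicate 3 and 0.27 without margin replicate 4.

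Purine synthesis and salvage genes were higher in 15 of 17 cases (median 0.20, camera adjusted p = 0.000457, adjusted p = 0.364 with an estimated correlation), with 0 passing over all genes and 3 when adjusted over the list alone: ADSSL1 (1.60 ± 0.36), PAICS (0.99 ± 0.26) and IMPDH2 (0.80 ± 0.25), enzymes of AMP, purine ring and GMP synthesis. Nuclear-encoded oxidative phosphorylation genes, among them COX6B1 (0.47 ± 0.27), were higher in 34 of 37 cases (median 0.20, camera adjusted p = 0.000255, adjusted p = 0.599 with an estimated correlation). Ribosomal protein genes were higher in 72 of 80 cases (median 0.14, camera adjusted p = 0.00259, adjusted p = 0.694 with an estimated correlation), although by means over cells their median was -0.01. No gene of the last 2 groups passed, also when adjusted over the list alone (0 and 0). The purine median was 0.31 without core replicate 3 and 0.41 without margin replicate 1, and the oxidative phosphorylation median was 0.38 without margin replicate 1 and 0.10 without margin replicate 4. The ribosomal call was lost without core replicate 1 (-0.02) or margin replicate 4 (0.01), and its median was 0.25, 0.22 and 0.32 without core replicate 2, core replicate 3 and margin replicate 1.

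Homeostatic microglia genes were lower in the core in 13 of 14 cases, with a median log2 change of -0.82, and 0 passed over all genes and 6 when adjusted over the list alone. Camera gave an adjusted p of 5.67e-08, with an adjusted p = 0.108 with an estimated correlation. In the paired fit 6 members fell over all genes, including P2RY12, P2RY13, CX3CR1, SALL1 and NAV3. Purinergic receptor genes were lower in 7 of 7 cases (median -0.39, camera adjusted p = 0.000333, adjusted p = 0.108 with an estimated correlation), with 0 passing over all genes and 2 when adjusted over the list alone. These were P2RY12 and P2RY13, which the homeostatic list also holds and which fell in the paired fit (log2 changes of -1.98 and -1.57). P2RX4 and P2RX7, channels opened by ATP, had unpaired changes of -0.36 ± 0.23 and -0.39 ± 0.32 and did not pass. Growth factor and receptor genes of microglia were lower in 15 of 15 cases (median -0.40, camera adjusted p = 0.0060, adjusted p = 0.364 with an estimated correlation), with IGF1 at -1.32 ± 0.43, MEF2C at -0.72 ± 0.33 and CSF1R at -0.66 ± 0.31. None passed over all genes or when adjusted over the list alone (0 and 0), and without margin replicate 4 the list's call was lost (median -0.24).

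Immediate-early genes, which also respond to tissue dissociation, were lower in the core in 21 of 22 cases, with a median of -0.66, and 0 passed over all genes or when adjusted over the list alone. Camera gave an adjusted p of 4.11e-06, with an adjusted p = 0.425 with an estimated correlation. Without core replicate 1 the median was -0.22 and the call was lost (camera adjusted p = 0.0799), and without core replicate 2 it was -1.09. In the paired fit 22 of 22 were lower and 2 fell, KLF2 and EGR3 (-2.61 ± 0.50). MHC class II presentation genes were lower in 11 of 12 cases (median -0.52, camera adjusted p = 0.00749, adjusted p = 0.399 with an estimated correlation) with 0 passing, also when adjusted over the list alone, and a paired median of -0.20; the call was lost without core replicate 3 (-0.49) or margin replicate 1 (-0.23). Complement genes were lower in 9 of 11 cases (median -0.31, camera adjusted p = 0.0453, adjusted p = 0.345 with an estimated correlation), with 0 passing over all genes and C3AR1 (-0.89 ± 0.25) as the 1 passing when adjusted over the list alone. C3 had a change of -0.52 ± 0.29. The complement call was lost in the paired fit (adjusted p = 0.113) and without core replicate 1 (-0.13), core replicate 2 (-0.39), margin replicate 1 (-0.13) or margin replicate 2 (-0.45), and without core replicate 3 the median was -0.50.

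ATP release and transport genes did not pass (8 of 12 higher, median 0.31, camera adjusted p = 0.131). PANX1, a channel that releases ATP, had a change of -0.26 ± 0.42 (SE) and SLC17A9, the vesicular nucleotide transporter, one of -0.17 ± 0.36. Genes that turn over extracellular nucleotides did not pass (8 of 11 lower, median -0.31, camera adjusted p = 0.357) and fell as a list in the paired fit (median -0.47, camera adjusted p = 0.0164, adjusted p = 0.506 with an estimated correlation). ENTPD1, which degrades extracellular ATP, had a change of -0.58 ± 0.34, and NT5E, with 36 and 19 UMIs, did not pass the low-count filter. The mitochondrially encoded list (median -0.28, camera adjusted p = 0.0713) and the inflammatory list (-0.18 and 0.218) passed only in the paired fit, with medians of -0.47 and -0.43 and camera adjusted p of 0.00201 and 0.0442, and adjusted p = 0.593 and 0.742 with an estimated correlation. Lists that passed in neither fit were interferon response (-0.51), immunoregulation (-0.32), MHC class I (-0.19), heat shock (-0.03) and NK cell genes (-1.21). Of the 23 interferon genes 20 were lower in core without pairs and 19 higher in the paired fit (median 0.13, camera adjusted p = 0.0918), so their direction is not settled. The oligodendrocyte (-0.31), astrocyte or tumour cell (-1.42) and erythroid cell lists (0.79, with a test direction of down) did not pass without pairs and were not tested in the paired fit, where too few of their genes remained. Among other genes reported in any case, TMEM119 (-0.70 ± 0.43), CD163 (0.90 ± 0.91), SPP1 (0.94 ± 0.40), VEGFA (0.91 ± 0.43) and IL1B (-0.48 ± 0.74) did not pass. The T cell, B or plasma cell, neutrophil, neuron and endothelial lists had under 3 tested genes. T cell markers were at 31.2, 0 and 92.4 CPM in core replicates 1 to 3 and at most 7.61 in the margin libraries.

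Of the 28 lists, 16 passed by camera in all cells and 18 of 25 in the paired fit. With an estimated correlation 0 passed in either fit, and fry called 5 lists without pairs: homeostatic microglia, purinergic receptors, hypoxia response, glycolysis and cell cycle. With pairs fry called 0 of 25 lists, with a lowest adjusted p of 0.157 for homeostatic and macrophage genes. An exact permutation of list medians over the 35 splits gave p of 0.0571 for macrophage, glycolysis, immunoregulation and cell cycle genes and 0.0857 for hypoxia and homeostatic genes, with adjusted values of 0.343 or more. Camera calls are therefore loose here: other splits of the same libraries gave up to 16 called lists.

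List medians moved when macrophage-like classes were left out, a comparison chosen after the data were seen. The removed classes were named by macrophage markers. They include the cluster of 456 cells whose top genes began with SLC2A1, HILPDA, ADM and HK2, members of the hypoxia list. Smaller hypoxia and macrophage medians were therefore largely set by the choice of cells and do not show where the change lies. Without those cells the hypoxia median was 0.49, glycolysis 0.50, macrophage markers 0.26, homeostatic genes -0.43, iron genes 0.22, matrix genes 0.25 and purinergic receptors -0.71, and each of these lists still passed by camera (adjusted p of 0.0367 or less; adjusted p = 0.101 or more with an estimated correlation). MHC class II genes lost the call and turned to a median of 0.0403 (camera adjusted p = 0.718), and complement (-0.20, 0.348) and lipid handling (0.13, 0.0558) lost theirs. Interferon (-0.68, camera adjusted p = 0.0002), inflammatory (-0.08, 0.00762) and oligodendrocyte genes (-0.69, 0.0426) gained a call as lower in core, with adjusted p = 0.552 or more with an estimated correlation. For interferon genes the paired fit of all cells pointed the other way, as given above. No gene passed (0 by edgeR, 312 at an unadjusted p under 0.05).

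**Figure D3:**
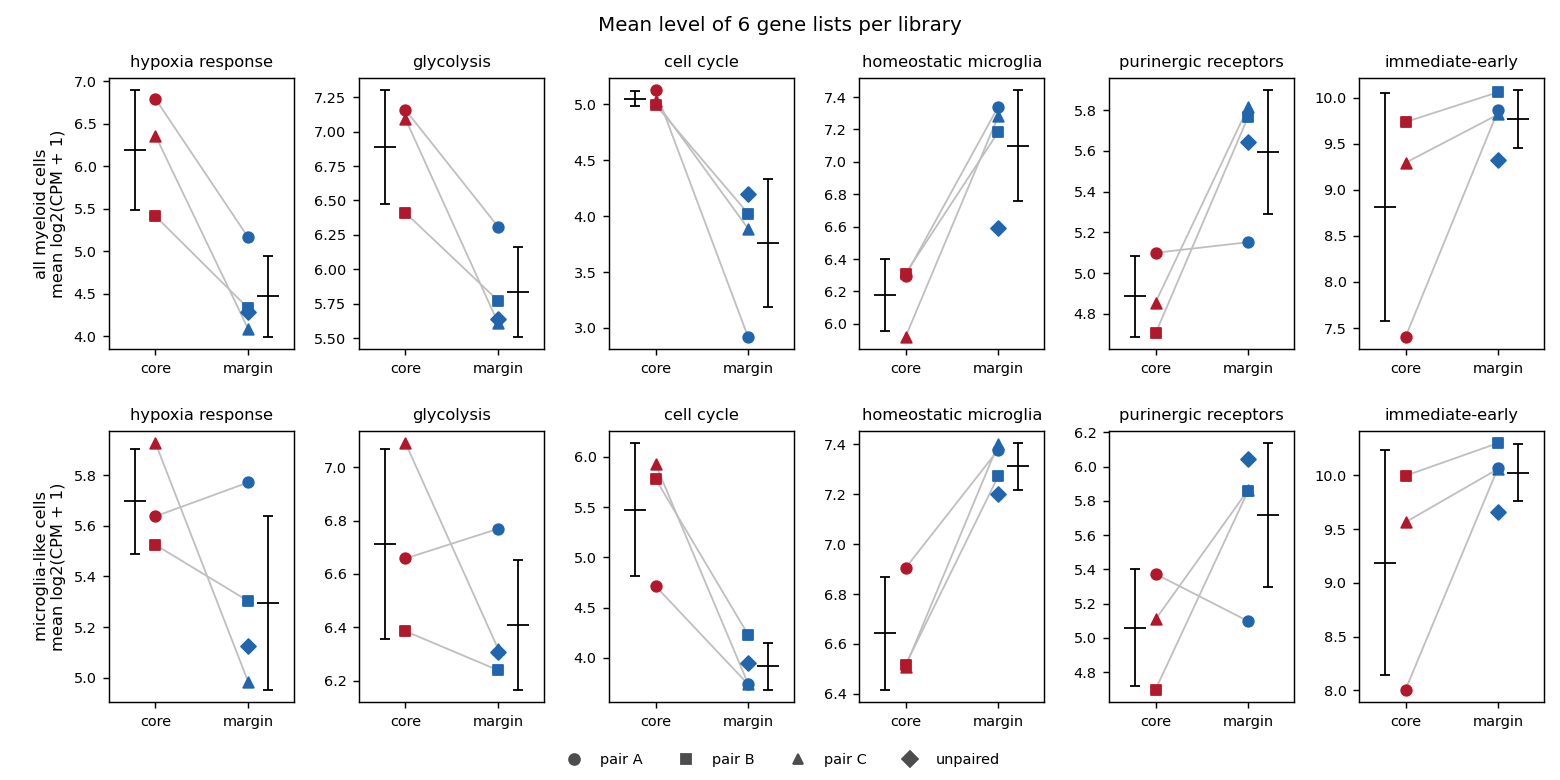
Mean log2 CPM of 6 gene lists per library, in all myeloid cells and in microglia-like cells; points are libraries, grey lines join pairs, and black bars are means with standard deviations. The hypoxia score differed by 1.72 ± 0.47 (SE) in all cells and by 0.40 ± 0.21 (SE) in microglia-like cells.

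Within microglia-like cells, no gene passed without pairs, so the genes with the smallest p are given. P2RY12 was at 46.9 ± 3.07 CPM (SD, n = 3) in core and 123 ± 22.9 CPM (SD, n = 4) in margin libraries, a log2 change of -1.39 ± 0.28 (SE; edgeR adjusted p = 0.357). The proliferation marker MKI67 had 153 UMIs in core and 1 in margin libraries, a ratio of 86.2 (counting interval 15.3 to 3428, edgeR adjusted p = 0.142). Few cells carried them: 7 of 449, 1 of 20 and 10 of 90 microglia-like cells of core replicates 1 to 3. The counting interval takes UMIs as independent, which those of 1 cell are not. Class naming also shapes this ratio, since a cluster with MKI67 among its top genes was named macrophage-like. All 23 MKI67 UMIs of margin replicate 4 lay in 1 macrophage-like cell. Over all cells MKI67 had 838, 7 and 143 UMIs in core replicates 1 to 3. Margin replicates 1 to 4 had 42, 1, 6 and 23. The other genes with small p were CENPF (2.72 ± 0.44), the integrin ITGA4 (3.03 ± 0.50), BNIP3 (3.23 ± 0.65), the histone gene HIST1H1D (2.30 ± 0.53), CACNA1A (-2.15 ± 0.39), AC027031.2 (-2.02 ± 0.37), ZNF711 (-2.92 ± 0.58) and PDK4 (-2.74 ± 0.55). Unpaired edgeR called 0 of 8838 genes, with 340 at an unadjusted p under 0.05, DESeq2 called 11, and edgeR without core replicate 1 called 6. In 180 genes every core library lay above every margin library and in 254 below, 4.91% of the genes against 5.71% by chance. Libraries fall in different clusters of this class: core replicate 1 has 324 and 121 of its 449 cells in 2 clusters that also hold 7 and 12 of the 44 cells of its partner, margin replicate 2, and at most 8 cells each of any other library. Margin replicate 1 has 83 of 106 in another, and core replicate 2, core replicate 3, margin replicate 2, margin replicate 3 and margin replicate 4 have 20 of 20, 80 of 90, 25 of 44, 195 of 200 and 64 of 69 in a further cluster. Core against margin within this class therefore also compares clusters.

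In the paired fit 14 of 8434 genes passed, 7 higher and 7 lower in core. S100A10 (2.88 ± 0.42), ITGA4 (2.80 ± 0.50), HIST1H1D (2.73 ± 0.39) and CENPF (2.73 ± 0.45) rose, as did MKI67. DHRS9 (-3.42 ± 0.51), CACNA1A (-2.37 ± 0.38), PDK4 (-2.35 ± 0.37), the TNF family ligand TNFSF18 (-2.33 ± 0.41) and MIR222HG (-1.71 ± 0.29) fell. CCL2 also fell, by a log2 change of -2.39 ± 0.38, with overlapping ranges. Adjusted p of these genes ran from 0.0203 to 0.0445 (edgeR). Leaving out the pair of core replicate 1, of core replicate 2 or of core replicate 3 gave 78, 0 and 56 calls. With classes from a clustering without the called genes, 2 genes passed without and 24 with pairs.

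Purinergic receptor genes were lower in core in 6 of 7 cases within microglia-like cells, with a median log2 change of -0.72. Camera gave an adjusted p of 0.000217, with an adjusted p = 0.184 with an estimated correlation. Of them 0 passed over all genes and 3 when adjusted over the list alone: P2RY12, P2RY13 (-1.14 ± 0.33) and P2RX4 (-0.77 ± 0.28). P2RX7 (-0.72 ± 0.34), PANX1 (-0.88 ± 0.55), SLC17A9 (-0.38 ± 0.37) and ENTPD1 (-0.30 ± 0.38) did not pass. Homeostatic genes were lower in 12 of 14 cases (median -0.45, camera adjusted p = 5.56e-07, adjusted p = 0.0601 with an estimated correlation), with 0 passing over all genes and 4 when adjusted over the list alone. SALL1 had a change of -1.74 ± 0.45 and NAV3 of -1.53 ± 0.43, against -0.21 ± 0.31 for TMEM119 and -1.08 ± 0.41 for CX3CR1. Without core replicate 1 that median was -0.97. With classes clustered without called genes, it was -0.43 (camera adjusted p = 2.16e-07, adjusted p = 0.0486 with an estimated correlation), and with pairs in those classes -0.67 (adjusted p = 0.389 with an estimated correlation). An exact permutation of list medians gave p = 0.0286 for purinergic receptors, the smallest it can give, and 0.457 after adjustment over 24 lists.

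Cell cycle genes were higher in 11 of 11 cases (median 1.17, camera adjusted p = 4.51e-08, adjusted p = 0.186 with an estimated correlation), with 0 passing over all genes and 6 when adjusted over the list alone, TYMS (2.50 ± 0.72) among them. Without core replicate 1 the median was 2.66. The mean log2 CPM of the cell cycle list differed by 1.56 ± 0.40 (SE) in these cells. With classes clustered without called genes that difference was smaller, at 0.68 ± 0.34 (SE). Macrophage markers were higher in 11 of 13 cases (median 1.11, camera adjusted p = 5.56e-07, adjusted p = 0.186 with an estimated correlation), with 0 passing over all genes and 4 when adjusted over the list alone, among them TGFBI (1.96 ± 0.50) and EMILIN2 (1.86 ± 0.52). That median moved to 0.35 without core replicate 1, 0.39 without core replicate 3, and 0.70, 0.43 and 0.68 without margin replicates 1, 3 and 4. The homeostatic and macrophage lists hold the markers that named the clusters. Hypoxia genes were higher in 12 of 16 cases (median 0.26, camera adjusted p = 0.00245, adjusted p = 0.186 with an estimated correlation), with 0 passing over all genes and 1, BNIP3, when adjusted over the list alone. The median was 0.45 without core replicate 2, 0.49 without margin replicate 2 and 0.12 without margin replicate 4, and the call was lost in the paired fit (0.21, camera adjusted p = 0.0915) and with sums thinned to the smallest library (0.31 over 11 genes, camera adjusted p = 0.0642). With classes clustered without these genes, chosen after the data were seen, the hypoxia median was 0.52 without pairs (camera adjusted p = 5.23e-06, adjusted p = 0.0486 with an estimated correlation). With pairs it was 0.46 (camera adjusted p = 0.000104, adjusted p = 0.389 with an estimated correlation). Glycolysis genes were higher in 12 of 15 cases (median 0.45, camera adjusted p = 0.000217, adjusted p = 0.308 with an estimated correlation), with 0 passing and LDHA at 0.89 ± 0.35. Without core replicate 2 that median was 0.71. The difference between all cells and microglia-like cells was not tested.

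Purine synthesis (16 of 16 higher, median 0.31, IMPDH2 at 0.70 ± 0.27), oxidative phosphorylation (36 of 37, 0.23, ATP5F1A at 0.53 ± 0.25) and ribosomal protein genes (74 of 79, 0.18) were higher in core microglia-like cells. Their camera adjusted p were 0.000111, 6.04e-07 and 6.01e-06, with adjusted p = 0.308, 0.455 and 0.607 with an estimated correlation. Immediate-early genes (22 of 22 lower, median -0.50, EGR1 at -1.35 ± 0.41), growth factor genes (15 of 15, -0.31), interferon genes (20 of 22, -0.75, OAS1 at -1.54 ± 0.56) and inflammatory genes (14 of 23, -0.06, TNF at -1.13 ± 0.46 and CCL20 at 2.24 ± 0.79) were lower. Their camera adjusted p were 6.12e-08, 0.00495, 0.000454 and 0.0208, with adjusted p = 0.308, 0.308, 0.607 and 0.742 with an estimated correlation. None of their members passed, also when adjusted over the list alone (0 for each). Without core replicate 1 the immediate-early median was -0.22, the interferon and ribosomal calls were lost (-0.26 and 0.02) and the inflammatory list was higher in core (0.30). The interferon call was also lost without margin replicate 1 (-0.30) and in the paired fit, the inflammatory call without margin replicate 3 (0.06), and the growth factor call without core replicate 2 (-0.10) or margin replicate 4 (-0.19). Medians also moved for interferon genes without core replicates 2 and 3 (-1.13 and -1.37), inflammatory genes without core replicates 2 and 3 and margin replicates 2 and 4 (-0.26, -0.79, -0.17 and 0.008), and immediate-early genes without core replicate 2 (-0.88). So did those of ribosomal genes without core replicate 2 and margin replicates 1 and 4 (0.29, 0.41 and 0.07), oxidative phosphorylation without margin replicates 1 and 4 (0.46 and 0.12), and purine synthesis without core replicate 3 or margin replicate 4 (0.20 each). Lists of ATP release (median 0.07), nucleotide turnover (-0.15), mitochondrially encoded (-0.17), immunoregulation (-0.21), lipid handling (0.09), MHC class II (0.04), MHC class I (-0.12), complement (-0.18), heat shock (-0.18), iron (0.02) and matrix genes (0.36) did not pass. In the paired fit the mitochondrially encoded, lipid and matrix lists also passed (camera adjusted p = 0.0156, 0.00033 and 0.0292; adjusted p = 0.717, 0.561 and 0.690 with an estimated correlation). CD163 (1.11 ± 1.25), SPP1 (0.55 ± 0.50), VEGFA (1.10 ± 0.62) and IL1B (-0.06 ± 0.70) did not pass.

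Within TMEM119-positive cells, the population the study compared, IBSP (bone sialoprotein, a secreted matrix protein) rose in the core: 154 ± 3.37 CPM (SD, n = 2) against 0 CPM in 4 of 4 margin libraries. The core libraries held 1296 UMIs and the margin libraries 0 (edgeR adjusted p = 0.00579, and 0.0447 in the paired fit over 2 pairs). With a floor of 3 counts over the margin group the ratio is 184. That ratio is no lower bound, since the floor takes UMIs as independent. IBSP UMIs lay in few cells, with up to 411 in 1 cell among all cells of core replicate 1. The 0 covers 107, 38, 171 and 58 TMEM119-positive cells of margin replicates 1 to 4. Core replicate 2 had 17 such cells, too few to enter, and none of its 41 cells had a UMI of IBSP. At a median of 7421 UMIs this bounds the share of cells with a detected UMI at 8.60% (exact upper limit), not expression. IBSP lies on chromosome 4 from 87799581 to 87812435. It was seen in 5.66% of all cells of core replicate 1 (exact interval 4.58% to 6.91%) and 5.63% of core replicate 3 (3.37% to 8.74%). Unpaired edgeR called 1 of 9201 genes, with 436 at an unadjusted p under 0.05, and DESeq2 called 20. With pairs 3 passed: IBSP, the metallothionein MT1E (4.20 ± 0.42) and SPARCL1 (5.60 ± 0.53). The core and margin ranges of SPARCL1 overlapped. In the second clustering SPARCL1 was among the top 10 genes of a cluster of 38 cells with the highest fold for astrocyte or tumour cell markers. Whether such cells account for its change was not tested. Calls numbered 8, 4 and 2 without core replicate 3, margin replicate 2 and margin replicate 3, and IBSP passed with each library left out, where a lone core library is assumed to vary like the margin group. In 512 genes both core libraries lay above every margin library and in 556 below, 11.6% of the genes against 13.3% by chance.

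In these cells P2RY12 was at 44.4 ± 2.83 CPM (SD, n = 2) in core and 133 ± 21.9 CPM (SD, n = 4) in margin libraries, a log2 change of -1.58 ± 0.32 (SE; edgeR adjusted p = 0.338). Homeostatic genes were lower in 12 of 14 cases (median -0.47, camera adjusted p = 9.81e-06, adjusted p = 0.121 with an estimated correlation), and 3 passed when adjusted over the list alone. Purinergic receptors were lower in 7 of 7 (median -0.45, camera adjusted p = 0.00108, adjusted p = 0.121 with an estimated correlation), with P2RY12 as the 1 passing when adjusted over the list alone. Immediate-early genes were lower in 22 of 22 (median -1.0, BTG2 at -1.46 ± 0.43, camera adjusted p = 1.46e-13, adjusted p = 0.323 with an estimated correlation). Interferon genes were lower in 22 of 23 (median -1.34, IFIT2 at -1.90 ± 0.66) and inflammatory genes in 16 of 25 (median -0.29). Their camera adjusted p were 8.21e-06 and 0.00204, with adjusted p = 0.644 and 0.722 with an estimated correlation, and both calls were lost in the paired fit. Without core replicate 1 the homeostatic median was -1.03, the immediate-early median -0.39, the interferon call was lost (-0.64) and the inflammatory list was higher in core (0.59). Without core replicate 3 these medians were -0.28, -2.38, -2.53 and -2.35, and the purinergic call was lost (-0.63). Leaving out margin libraries moved the purinergic median to -0.27 (margin replicate 4), the interferon median to -0.84 (margin replicate 1) and the inflammatory median to -0.17 and -0.11 (margin replicates 3 and 4).

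Hypoxia genes were higher in TMEM119-positive core cells in 18 of 19 cases (median 0.73, camera adjusted p = 3.93e-09, adjusted p = 0.121 with an estimated correlation), and 5 passed when adjusted over the list alone, among them BNIP3 (3.26 ± 0.59), ERO1A (1.39 ± 0.29) and HILPDA (2.51 ± 0.57). Glycolysis genes were higher in 13 of 16 (median 0.87, camera adjusted p = 3.22e-10, adjusted p = 0.0907 with an estimated correlation), with 7 passing when adjusted over the list alone, such as ENO1 (1.23 ± 0.31). Cell cycle genes were higher in 14 of 14 (median 1.49, camera adjusted p = 5.46e-12, adjusted p = 0.121 with an estimated correlation), with 7 passing when adjusted over the list alone, such as TOP2A (3.42 ± 0.61) and CDK1 (2.88 ± 0.58). Macrophage markers were higher in 11 of 13 (median 1.58, camera adjusted p = 4.76e-07, adjusted p = 0.228 with an estimated correlation), with 5 passing when adjusted over the list alone, such as TGFBI (2.60 ± 0.51). Over all genes 0 members of any list passed. The macrophage median was 0.96 without core replicate 1 and the cell cycle median 2.43 without core replicate 3. TMEM119-positive cells were not all microglia-like by class. In core replicates 1 and 3, 266 of 493 and 60 of 84 were. In margin replicates 1 to 4 the counts were 75 of 107, 30 of 38, 130 of 171 and 49 of 58. These list changes can therefore also reflect the mix of classes, which was not tested here.

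Purine synthesis (17 of 17 higher, median 0.34, NME1 at 0.86 ± 0.41), oxidative phosphorylation (36 of 37, 0.22), ribosomal protein (68 of 79, 0.26) and iron genes (8 of 12, 0.05, HAMP at 2.21 ± 0.71) were also higher. Their camera adjusted p were 0.00011, 3.84e-05, 2.61e-06 and 0.0187, with adjusted p = 0.396, 0.644, 0.644 and 0.340 with an estimated correlation, and 0 members passed when adjusted over the list alone. The ribosomal call was lost without core replicate 1 (0.10), and the iron call without core replicate 3 (0.15) or margin replicate 4 (0.04). The iron call was also lost with sums thinned to the smallest library, where 4 of 10 genes were higher (median -0.059, camera adjusted p = 0.175). The iron median was 0.32, 0.45, 0.17 and 0.20 without core replicate 1 and margin replicates 1, 2 and 3. Oxidative phosphorylation had medians of 0.34, 0.44 and 0.12 without core replicate 1, margin replicate 1 and margin replicate 4. Ribosomal medians were 0.41, 0.51 and 0.12 without core replicate 3, margin replicate 1 and margin replicate 4, and the purine median was 0.22 without margin replicate 4. Lists that did not pass were ATP release (0.16), nucleotide turnover (-0.26), mitochondrially encoded (-0.34), immunoregulation (-0.11), lipid handling (0.06), MHC class II (0.10), MHC class I (-0.18), complement (-0.09), heat shock (-0.16, with a test direction of up), matrix (0.42), growth factor (-0.23), NK cell (-1.72), oligodendrocyte (-0.21) and astrocyte or tumour cell genes (0.51, with a test direction of down). In the paired fit nucleotide turnover, mitochondrially encoded, lipid, MHC class II, growth factor and oligodendrocyte lists passed as well, with camera adjusted p of 0.0136, 1.74e-08, 0.00638, 0.00306, 0.000287 and 0.0252 and adjusted p = 0.534 or more with an estimated correlation. Of the genes reported in any case, P2RY13 (-1.01 ± 0.38), P2RX4 (-0.69 ± 0.30), P2RX7 (-0.45 ± 0.39), CX3CR1 (-1.06 ± 0.45), TMEM119 (-0.49 ± 0.34), PANX1 (-0.60 ± 0.56), SLC17A9 (-0.53 ± 0.51), ENTPD1 (-0.08 ± 0.41), CD163 (1.58 ± 1.30), SPP1 (0.79 ± 0.54), VEGFA (0.73 ± 0.66), IL1B (-0.29 ± 0.95) and CCL2 (-1.08 ± 1.2) did not pass without pairs.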

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

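No explanation was tested for the values in this part. The 4 margin libraries were compared with each other by a Dixon test with the critical ratio for 4 values, and 19 of 191 groups of values held a value standing apart, against 5% by chance. In 3 of these groups the other 3 values were 0, so the outcome was fixed whatever the fourth value: SLAMF9, COL27A1 and MKI67, on 3, 1 and 1 UMIs. Without them it is 16 of 188. In margin replicate 1, microglia-like cells made up 19.8% of cells (63.3% to 68.8% in the other margin libraries), border-associated macrophage-like cells 26.9% (0% to 0.917%) and TMEM119-positive cells 19.96% (53.2% to 59.4%). Margin replicate 2 had a median mitochondrial share per cell of 3.24% (0.978% to 1.33%). In all myeloid cells of margin replicate 2, FN1 was at 24.2 CPM (0 to 2.03), ANGPTL4 at 9.23 CPM (0 to 1.01), COL27A1 at 1.15 CPM (0 in the others) and SLC17A9 at 18.5 CPM (9.63 to 9.95). SLAMF9 was at 0.995 CPM in margin replicate 1 and 0 in the others.

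In microglia-like cells, MKI67 was at 0.905 CPM in margin replicate 1 (0 in the others). Margin replicate 4 had SALL1 at 83.5 CPM (27.0 to 31.7), P2RX7 at 93.1 CPM (45.2 to 49.5) and CCL2 at 3274 CPM (290 to 709). Margin replicate 2 had TGFBI at 45.5 CPM (9.68 to 13.9) and CD163 at 413 CPM (0 to 19.6). In TMEM119-positive cells, SALL1 was at 97.1 CPM (27.9 to 33.4) and CCL2 at 3875 CPM (254 to 741) in margin replicate 4. There, CD163 was at 443 CPM in margin replicate 2 (1.47 to 27.9) and CXCL2 at 19.5 CPM in margin replicate 1 (0 to 0.796).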

How the results depend on the processing

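Thinned sums, paired fits without a pair, removal of macrophage-like classes and the second clustering were chosen after the results were seen; the other alternatives were fixed before. In all myeloid cells the 3 called genes became 100 with DESeq2, 201 without a low-count filter and 0 above an average of 20 CPM. They became 191 with the pairs as a block, 93 with limma and a correlation between pairs, and 26 with limma on means over cells. There were 22 without doublet calls and cells with other markers, 5 with sums thinned to the smallest library, and 0 without macrophage-like classes. The paired fit gave 429, 112 and 60 genes without the pair of core replicate 1, 2 and 3, and leaving out single libraries gave 0 to 21. In microglia-like cells 0 became 11 with DESeq2, 150 without a low-count filter, 14 with the pairs as a block, 3 without doublet calls and other markers, 7 at the lower resolution, 2 with classes clustered without called genes, 24 with those classes and pairs, and 78 and 56 in the paired fit without the pair of core replicate 1 and 3. Leaving out single libraries gave 0 to 6. In TMEM119-positive cells 1 became 20 with DESeq2, 217 without a low-count filter, 3 with pairs as a block, 2 with limma and a correlation, 4 without doublet calls and other markers, 2 with at least 2 UMIs of TMEM119, 0 with thinned cells and 2 with thinned sums; single libraries left out gave 1 to 8. For the gene lists, an estimated correlation left 0 calls in all cells, 0 in microglia-like and 0 in TMEM119-positive cells, fry left 5, 1 and 3, and pairs with an estimated correlation left 0, 0 and 0. In the second clustering of microglia-like cells, 2 lists passed at an estimated correlation, hypoxia and homeostatic genes (adjusted p = 0.0486 for both). MHC class II genes had a median of 0.0403 in all cells without macrophage-like classes. Astrocyte or tumour cell genes were at 0.25 and 2.69 in all cells in the paired fit without the pair of core replicate 1 and 2, and interferon genes at 0.44 and 0.29 without the pair of core replicate 2 and 3. In microglia-like cells interferon genes were at -0.30 with a test direction of up and inflammatory genes at 0.11 without the pair of core replicate 1. Interferon genes were there at 0.11 without the pair of core replicate 2 and at 0.11 in the second clustering with pairs. In TMEM119-positive cells they were at -0.051 with pairs, again with a test direction of up. With single libraries left out, medians ran from -0.59 to 0.30 for inflammatory genes and -6.59 to 1.40 for erythroid genes in all cells. In microglia-like cells they ran from -1.37 to -0.26 for interferon and -0.79 to 0.30 for inflammatory genes. In TMEM119-positive cells they ran from -2.35 to 0.59 for inflammatory, -3.86 to 0.22 for oligodendrocyte and -2.25 to 0.63 for astrocyte or tumour cell genes. The share of monocyte-derived macrophage-like cells differed by 0 points at the lower resolution, 11.1 at the higher, 35.9 by marker sums and 0 after clustering without called genes. A value of 0 here means that no cluster took that name under the naming rule, as described above for the lower resolution. Over all named genes and alternatives, 1399 values in all cells had the same status, called or not called, 204 gained a call and 17 lost it. In microglia-like cells 1372 had the same status and 81 gained a call, where no gene was called and none could lose it. In TMEM119-positive cells, with 1 called gene, 925 had the same status and 28 gained a call. For lists, 293 had the same status, 26 gained a call, 22 lost it and 7 turned round in all cells, against 288, 26, 16 and 6 in microglia-like and 181, 20, 7 and 4 in TMEM119-positive cells. The sign differed with neither side passing in 6, 13 and 13 values. The planned comparison within macrophage-like cells and the test between classes gave no value, and other pseudocounts apply to other units. The cause of these differences was not tested.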

Other observations

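IBSP was concentrated in few cells. In core replicate 1, 39 of 1607 cells had at least 10 UMIs of IBSP and held 94.4% of its UMIs; 56.4% of these cells were macrophage-like by class, 20.5% border-like and 12.8% microglia-like. In core replicate 3, 12 of 320 cells held 97.9%, and 25% of them were macrophage-like, 41.7% border-like and 33.3% microglia-like. The myeloid genes CD74, C1QB and SPP1 were detected in 97.4%, 97.4% and 100% of the 39 cells and in 100% of the 12. The glial genes GFAP and PTPRZ1 were detected in 12.8% and 2.56% of the 39 cells and in 41.7% and 8.33% of the 12. By class, IBSP was seen in 2.23% of microglia-like, 8.54% of macrophage-like and 38.5% of border-like cells of core replicate 1, with median depths of 10702, 12663 and 9136.5 UMIs. The border-like share rests on 26 cells and was not seen in core replicate 3, where the shares were 5.56%, 8.33% and 6.42% at median depths of 21965.5, 10856 and 13706 UMIs.

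Of the tests below, the share of doublets among IBSP cells was written down before its result; all others were chosen after the result was seen. The higher hypoxia and glycolysis genes in core could reflect a different mix of cell classes. Within microglia-like cells clustered without these genes, the hypoxia score differed by 0.85 ± 0.11 (SE) and the glycolysis score by 0.53 ± 0.19 (SE), against 1.72 ± 0.47 and 1.05 ± 0.29 in all cells, so mix can neither be named as the cause nor ruled out. That class may itself not be free of other cells, as its macrophage markers were higher in core, with a median log2 change of 1.62. Whether other cells give that change was not tested. With all sums thinned to the smallest library, the hypoxia median in all cells was 0.999 against 1.05 over 17 genes. The glycolysis median was 1.11 against 1.22 over 14 genes. Thinning of sums leaves each gene's expected share of its library unchanged, so these medians had to stay near their values. The test therefore cannot decide on depth, and depth per cell was not tested. A single library does not account for the higher genes, as the lowest medians with 1 library left out were 1.15 for hypoxia and 1.04 for glycolysis genes. Neither depth nor a single library was tested as an explanation within microglia-like cells. There, thinned sums gave a hypoxia median of 0.31 over 11 genes against 0.26 over 16, so the call was lost without a smaller median. Low oxygen in the tumour core itself was not measured here.

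The lower immediate-early genes in core may rest on core replicate 1: without it the median was -0.22 against -0.66. With sums thinned to the smallest library the median was -0.68 against -0.66 over 22 genes, which cannot decide on depth for the reason given above. Handling stress cannot be told from these data, since the heat shock median was -0.0252 with a spread of 0.41 (SD) over 13 members.

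IBSP in core replicates 1 and 3 is not explained by RNA free in solution: the top 1% of cells in core replicate 1 held 70.7% of its UMIs, against at most 6.09% in 100 draws in proportion to depth, and those in core replicate 3 held 63.26% against at most 5.64%. Doublets or non-myeloid cells remain possible, as 37.3% of the 51 cells with at least 10 UMIs (19 cells, exact interval 24.1% to 51.9%) were doublet calls or carried markers of another class. Much of this is the general rate: 28.2% of these cells against 16.4% of all cells in core replicate 1, and 66.7% against 42.5% in core replicate 3.

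Called numbers were also counted for other groupings of the libraries. In all cells 3 of 35 splits, the real one included, called at least the 3 genes of the real split, and another split called 24, so libraries differ in ways other than region. In microglia-like cells the real split called 0 genes, which 35 of 35 splits must reach (highest other 9), so that count decides nothing. For lists, 4 of 35 splits reached the real 16 in all cells (highest other 16) and 4 of 35 the real 13 in microglia-like cells (highest other 15). With core and margin swapped within pairs, 1 of 4 arrangements, the real one, reached 191 genes in all cells (highest other 0) and 1 of 4 reached 14 in microglia-like cells (highest other 1), too few arrangements for a p under 0.05. Swapped pairs gave 13, 14 and 7 called lists against the real 18 in all cells, and 15, 9 and 9 against the real 14 in microglia-like cells. Among the 8 splits that part every pair, the real one called 3 genes in all cells and the others 0, while lists reached 16 against 16, and 14 against the real 13 in microglia-like cells. Counts of lists therefore could arise from groupings other than core and margin. Outside the real split, a count of 3 or more called genes in all cells arose only in splits that keep a pair together. Whether those splits called the same genes was not checked. At an unadjusted edgeR p under 0.05 the real split held 753 genes in all cells. Margin replicates 2, 3 and 4 against the rest held 1328, and core replicate 2 with margin replicates 2 and 4 held 760. Both of these splits part every pair. Some splits that do not part every pair held more than 753 as well, up to 1311. In microglia-like cells the real split held 340 genes, while others held up to 1120, and up to 802 where every pair was parted. These counts therefore show no excess for core against margin.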
